A study of Mus musculus with 16 samples.

How the data were processed

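The 16 libraries were made from sorted CD4 T cells with the SMART-Seq v4 kit for low input and Nextera XT, per the labels' protocols. The kit does not mark the strand of origin, so a value for a gene that overlaps another on the opposite strand is uncertain, as are values shared by near-identical genes such as Tgtp1 and Tgtp2. Reads were handled with fastp and STAR 2.7.3a on the mouse build mm10, and DESeq2 1.34.0 is also listed, per the submitters' processing notes. The program that counted reads and the release of its annotation are not given in the sources used here.

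The deposited table of raw counts holds whole numbers for 54957 genes in each library, with no normalization. The deposited TPM table holds transcript abundances that the authors scaled to one fixed total per sample. Within each of 7521 genes with more than 20 counts in every library, the ratio of count to TPM, scaled per library, was the same in all libraries to within rounding. Of the 54957 gene identifiers 54209 matched GENCODE M21 exactly, and symbols and coordinates come from that annotation (GRCm38, the assembly of mm10). No pair of libraries in a group was a copy of another: the lowest chi-square per degree of freedom between 2 of them was 44.3. The labels name no batch.

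Genes were tested from the raw counts with edgeR 4.0.16 in R 4.3.3: filterByExpr left 13621 genes, library sizes were scaled by TMM, and a robust quasi-likelihood fit used 1 coefficient for each of the 4 groups. The common dispersion was 0.444, a coefficient of variation of 0.667. The comparisons were exTh17 minus Th17 cells in joints and in lymph nodes, joint minus lymph node cells within each cell type, the mean of exTh17 minus Th17 over both tissues, and the difference of exTh17 minus Th17 between tissues. A gene is called, and said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are given with their standard error (SE), and levels as CPM (counts relative to the TMM-scaled library size) with the SD over the 4 libraries of a group. For a group with 0 counts the fold is a bound against a floor of 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so this floor covers counting error only.

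The named genes were fixed by a rule. It takes 18 set genes in every comparison, from Il17a to Cd3e, and the 8 genes with the largest fold in each direction among those called, with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. It also takes up to 4 members of each gene list by lowest p, and for the mean over tissues and the difference between tissues the 5 genes with the lowest p in each direction. Values are given for only part of the genes that the rule names. The groups, comparisons, tests, gene lists, this rule and the alternatives called planned were chosen before the data were examined. Differences in the number of genes with a count were tested by exact permutation.

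Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 34 lists of a comparison. The lists, of T cell programmes, responses and markers of other cells, came from general knowledge and hold 512 symbols, 6 of which are not in the files. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Of the 34 lists, fry called 4, 5, 14 and 14 in the joint, lymph node, Th17 and exTh17 comparisons.

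The fits were tested on simulated counts for the real genes and library sizes with known changes. At a true fold of 4 the fit recovered 29.2% of changed genes in the joint comparison (13298 genes tested) and 34.4% in the lymph node comparison (13305). Between tissues it recovered 53% in Th17 cells (13285) and 39.2% in exTh17 cells (13264). At a true fold of 2 these shares were 4%, 2.02%, 5.10% and 8.42%. False calls numbered 2, 1, 2 and 1. For the mean over tissues the shares were 66.3% and 27.8% (13289 genes, 4 false calls), and for the difference between tissues 20% and 2.06% (13269 genes, 1 false call). Changes of 2-fold in a single comparison were therefore rarely recovered. Apart from the known changes, the simulation gave each gene the same mean and spread in all 4 groups. It therefore does not cover the wider spread or the fewer detected genes of the joint Th17 libraries, and its false calls say nothing about these.

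The alternatives were other size factors (RLE, or library size alone), no filter or a stricter filter on low counts, the fit without robust estimation, a block of sets of 4 consecutive sample numbers, a fit of only the groups compared, an adjusted p under 0.1, a test against a fold of 1.5, DESeq2 1.42.0, limma voom with sample quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library in turn. Library size alone moved the median log2 fold of all genes by 0.11 in the joint comparison. No reads were available, so alignment and counting were not repeated.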

Results

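RNA was sequenced from sorted mouse CD4 T cells to compare Th17 cells with exTh17 cells, which had expressed Il17a in the past and no longer secreted IL-17A. The donors were TriTh17 mice, whose cells carry the red protein tdTomato once they have expressed Il17a. Their CD4 T cells were transferred into Rag2-deficient mice, which make no T or B cells of their own, and 20 mg of mannan, a yeast polysaccharide, was given to induce arthritis. Cells were taken 61 to 69 days later and stimulated with PMA and ionomycin, which activate T cells without engaging their antigen receptor. Cells positive for tdTomato were then sorted by IL-17A captured on their surface into Th17 (positive) and exTh17 (negative) cells, from lymph nodes and from joints. The 16 libraries form 4 groups of 4, and each is named here by its group and sample number. Total counts per library ran from 14360311 to 25556544. The labels do not say whether the samples of a group came from separate animals, so each p-value measures the spread between samples.

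Joint Th17 libraries held fewer genes with at least 1 count than the other groups, 14096 ± 249 (SD, n = 4), against 17050 ± 1023 in joint exTh17, 17843 ± 1441 in lymph node Th17 and 17517 ± 839 in lymph node exTh17 libraries. Joint Th17 differed from joint exTh17 and from lymph node Th17 cells with the smallest p that 4 against 4 can give (exact permutation test, two-sided, p = 0.0286 for each). The exact permutation test gave p = 0.686 between the lymph node groups and p = 0.486 between the exTh17 groups.

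**Figure D1:**
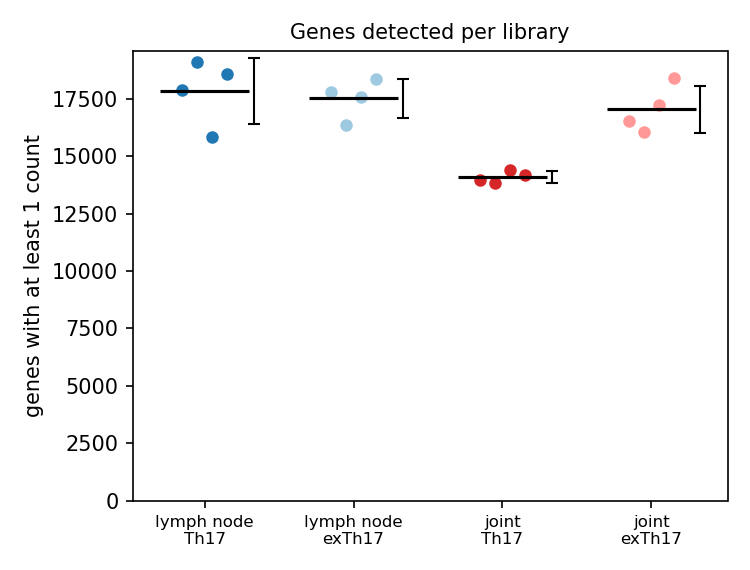
Number of genes with at least 1 count in each library (points), with the mean (line) and SD (bars) of each group of 4. The joint Th17 libraries lie lowest, at 14096 ± 249 genes.

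The comparison of exTh17 with Th17 cells within the joint asks how cells that have stopped secreting IL-17A differ from those that have not, in the inflamed tissue. In joint exTh17 cells the Th17 cytokine gene Il17f fell together with Il17a. Lef1, a transcription factor gene of naive and memory T cells, rose, as did Serpinb1a, which encodes a serine protease inhibitor, S1pr4, a receptor for sphingosine 1-phosphate on lymphocytes, and Hsph1, a chaperone. Vcam1, an adhesion molecule, and Mmp12, an elastase, fell. Markers of macrophages and fibroblasts lay below 0 in the same comparison, with list medians of -1.23 and -1.30. Whether RNA of such cells gave the falls of Vcam1 and Mmp12 was not tested. Tbx21, which encodes the transcription factor of the Th1 programme, did not pass the test.

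Il17a (ENSMUSG00000025929.4, mm10 chromosome 1, 20730905 to 20734496) defined the sort, so its level checks the labels and is not a finding. It averaged 373 ± 158 CPM (SD, n = 4) in joint exTh17 and 11671 ± 2093 CPM (SD, n = 4) in joint Th17 libraries, a log2 fold change of -4.97 ± 0.58 (SE, adjusted p = 5.09e-04). Il17f (ENSMUSG00000041872.9, mm10 chromosome 1, 20777146 to 20790617) averaged 205 ± 77.7 against 1436 ± 663 CPM (SD, n = 4 each), a log2 fold change of -2.81 ± 0.51 (adjusted p = 0.00838). Those were the only ones of the 18 genes fixed for every comparison to pass. Il22 had a log2 fold change of -1.25 ± 0.34 (adjusted p = 0.0564), Ifng of 0.71 ± 1.13 (0.910), Tbx21 of 0.19 ± 0.30 (0.907) and Csf2 of 1.13 ± 1.07 (0.807). Serpinb1a averaged 192 ± 42.7 against 50.8 ± 22.5 CPM (SD, n = 4 each), and its log2 fold change was 1.92 ± 0.39 (adjusted p = 0.0155). Lef1 rose by 2.91 ± 0.62 on the log2 scale (adjusted p = 0.0182), S1pr4 by 1.71 ± 0.44 (0.0466) and Hsph1 by 1.13 ± 0.27 (0.0337). Vcam1 changed by -1.75 ± 0.40 (adjusted p = 0.0263) and Mmp12 by -1.46 ± 0.36 (0.0363). The calls of Il17a, Il17f, Lef1 and Serpinb1a held without each of the 8 joint libraries in turn. Leaving out 1 library at a time ended the call of Vcam1 without joint Th17 3, joint exTh17 4 or joint exTh17 16 (adjusted p up to 0.0797). It ended that of Mmp12 without joint exTh17 4, 8 or 12 or joint Th17 15 (up to 0.0940), that of Hsph1 without joint Th17 3, 7 or 11 or joint exTh17 4, 8 or 16 (up to 0.0912), and that of S1pr4 without joint Th17 3, 7 or 15 or joint exTh17 8, 12 or 16 (up to 0.126). On log2(TPM + 1) the calls of Lef1, Hsph1, Mmp12 and Vcam1 ended, and limma with sample quality weights ended all of these calls but that of Il17a. The block of sets of 4 consecutive sample numbers, which the labels do not name, ended those of S1pr4, Mmp12 and Vcam1.

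In the joint 347 of 13621 genes were called, 326 higher and 21 lower in exTh17 cells. Most of the higher genes were scarce: their median log2 CPM was 0.29, against 3.97 for all tested genes. Trmt44 (ENSMUSG00000029097.11, mm10 chromosome 5, 35556203 to 35575070), a tRNA methyltransferase gene, averaged 10.3 ± 1.43 CPM in joint exTh17 and 0.0984 ± 0.0488 CPM in joint Th17 libraries (SD, n = 4 each), a log2 fold change of 6.63 ± 0.61 (adjusted p = 3.48e-05). It averaged 12.9 ± 5.17 and 11.9 ± 1.37 CPM in lymph node Th17 and exTh17 libraries. Relt, a TNF receptor family gene, rose by 5.10 ± 0.66 (adjusted p = 0.00122). Of the 326 higher genes, 314 were also called lower in joint than in lymph node Th17 cells. Their median log2 fold change between joint and lymph node exTh17 cells was 0.23. These genes were chosen by their levels in the joint libraries, so their folds were also read in libraries that did not choose them, in a check added after the values were seen. Genes called higher with 2 libraries of each joint group numbered 160 to 549 over 6 ways of taking the 2. Their median log2 fold of group mean CPM was 4.81 to 5.19 in the libraries that chose them and 0.22 to 1.32 in the others (groups under 3 counts set to 3). Chosen with 2 joint Th17 libraries, such genes had a median of -4.29 to -4.85 there against lymph node Th17 libraries, and of -0.55 to -1.44 in the other 2. Most of the size of these folds was therefore not seen in the libraries left out of the choice. Chosen with 2 joint exTh17 libraries, such genes had a median of 0.14 to 0.45 there against lymph node exTh17 libraries. In the other 2 the median was -0.58 to -0.29, so the positive 0.23 was not seen there either.

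The spread within groups was unequal. The mean SD of log2(CPM + 1) was 0.81 in joint Th17 libraries and 0.42 to 0.46 in the other groups, and the shared estimate averages these. The count of 347 depended on the model: DESeq2 called 1072 genes, limma with sample quality weights called 1, and edgeR fitted to these 8 libraries alone called 1. The gene that limma called was Il17a, which the sort fixed as lower. The gene that edgeR called was among the 347 and was also lower in exTh17 cells. The count was 223 without joint exTh17 16, and 178 with the block of sets of 4 consecutive sample numbers. The 21 lower genes were 9 with library size alone as the scaling and 6 on log2(TPM + 0.1). They were 4, 9, 7 and 6 without joint exTh17 4, 8, 12 or 16.

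By camera 6 gene lists were called in the joint, and none of these calls held after adjustment with an estimated correlation between genes, where the lowest adjusted p over the 34 lists was 0.102. The list of the Th17 programme had a median log2 fold change of -0.40, and 2 of its 20 tested members fell (3 adjusted over the list alone). The 2 were Il17a, which the sort fixed as lower, and Il17f. The list was not tested without Il17a, so the sort contributes to its call. The 13 genes of lymph node homing and egress all had positive folds, with Lef1 and S1pr4 passing over all genes tested and adjusted over the list alone. The call of S1pr4 over all genes ended with the block of sets of 4 consecutive sample numbers. The 13 genes of cytotoxicity, the granule proteins and receptors of killer cells, were also all positive, with a median of 1.05; none passed over all genes, and 3 rose adjusted over the list alone. Markers of NK cells lay above 0 as well, with a median of 2.48 and 4 of 6 positive, Gzma being in both lists; 1 rose, 3 adjusted over the list alone (camera adjusted p = 0.876). Those of CD8 and gamma-delta T cells had a median of 0.90, with 3 of 4 positive and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.340). Those of B and plasma cells had a median of 2.74, with 3 of 5 positive; 1 rose, 3 adjusted over the list alone (camera adjusted p = 0.0800, fry adjusted p = 0.0196). Such genes are scarce, and joint Th17 libraries held fewer distinct genes than the other groups. Prf1, the perforin gene, averaged 4.53 ± 2.49 against 0.263 ± 0.479 CPM (SD, n = 4 each; log2 fold change 4.12 ± 1.14, adjusted p = 0.0664). The chemokine list (median -0.77, 0 of 16 passing) lay below 0, and the markers of macrophages (median -1.23, 0 of 15) and of fibroblasts (median -1.30, 0 of 16) did so beside it. For those 3 lists 0 members passed adjusted over the list alone as well. Dcn, a fibroblast proteoglycan gene, averaged 102 ± 67.6 against 309 ± 232 CPM, and Cd14, a monocyte receptor gene, 84.9 ± 66.0 against 225 ± 159 CPM (SD, n = 4 each). The camera adjusted p was 2.38e-04 for the Th17 programme, 0.0197 for homing, 0.00192 for cytotoxicity, 0.00243 for chemokines, 0.0203 for macrophage and 0.00192 for fibroblast markers. Without joint Th17 15 the homing call ended (adjusted p = 0.174). The chemokine call ended without joint exTh17 4 (median -0.36, adjusted p = 0.176), and its median was -0.48 without joint Th17 15. The macrophage call ended without joint Th17 3 or 15 or joint exTh17 4 or 8, with medians of -1.12, -0.29, -0.80 and -0.93 (adjusted p up to 0.251), and its median was -1.95 without joint exTh17 16. With the block of sets of 4 consecutive sample numbers, which the labels do not name, the macrophage median was -0.64 and the call stayed (adjusted p = 0.0108). The fibroblast call ended without joint Th17 3 or 15 or joint exTh17 4, with medians of -1.02, -0.97 and -0.91 (adjusted p up to 0.206). The Th17 programme kept its call without each library, with a median of -0.25 without joint exTh17 16. With an estimated correlation between genes the unadjusted p was 0.0443, 0.0211, 0.00300, 0.122, 0.252 and 0.238 in the same order. Over all 6 comparisons camera called 31 lists in the pairwise comparisons, 11 for the mean over tissues (2 up and 9 down) and 3 for the difference between tissues, and 0 of these calls held after adjustment with an estimated correlation. With it 13 of the 31, 8 of the 11 and 2 of the 3 had an unadjusted p under 0.05, and fry called 37 lists in the pairwise comparisons.

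The same comparison in lymph nodes asks whether exTh17 and Th17 cells already differ outside the inflamed tissue. Lymph node exTh17 cells had less of the Th17 cytokine transcripts Il17f and Il22 and of Tnfsf11, which encodes the osteoclast factor RANKL. Early genes of T cell activation such as Nr4a1, Fos and Dusp1 fell as well. Genes of interferon-inducible GTPases, which act against microbes inside cells, rose: Iigp1, Gbp2, Tgtp1 and Tgtp2. Ltb, which encodes lymphotoxin beta, also rose.

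Il17a averaged 926 ± 818 CPM (SD, n = 4) in lymph node exTh17 and 18529 ± 12592 CPM (SD, n = 4) in lymph node Th17 libraries (log2 fold change -4.32 ± 0.56, adjusted p = 0.00233). Il17f changed by -3.10 ± 0.52 (adjusted p = 0.0119). Il22 (ENSMUSG00000074695.3, mm10 chromosome 10, 118204942 to 118210047) averaged 1294 ± 545 against 4204 ± 1931 CPM (SD, n = 4 each), a change of -1.70 ± 0.34 (adjusted p = 0.0238). Tnfsf11 averaged 389 ± 170 against 1570 ± 833 CPM (SD, n = 4 each; -2.01 ± 0.37, adjusted p = 0.0164). Csf2, which encodes GM-CSF, changed by -5.95 ± 1.32 (adjusted p = 0.0426), from 100.1 ± 150.5 to 1.61 ± 1.40 CPM (SD, n = 4 each). Those 5 of the 18 fixed genes passed; Ifng (-0.43 ± 1.12, adjusted p = 0.981) and Tbx21 (-0.08 ± 0.30, 0.986) did not. Iigp1 (ENSMUSG00000054072.12, mm10 chromosome 18, 60376027 to 60392634) averaged 224 ± 106 against 47.0 ± 4.53 CPM (SD, n = 4 each) and rose by 2.25 ± 0.29 (adjusted p = 0.00233). Gbp2 rose by 2.02 ± 0.34 (adjusted p = 0.0119), Tgtp1 by 1.82 ± 0.38 (0.0285) and Tgtp2 by 1.69 ± 0.35 (0.0317); reads of this near-identical pair can be assigned to either gene. Ltb averaged 1339 ± 414 against 494 ± 196 CPM (SD, n = 4 each; 1.44 ± 0.29, adjusted p = 0.0256). Nr4a1 changed by -2.34 ± 0.42 (adjusted p = 0.0145), Fos by -2.22 ± 0.43 (0.0195) and Dusp1 by -1.72 ± 0.28 (0.0119).

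**Figure D2:**
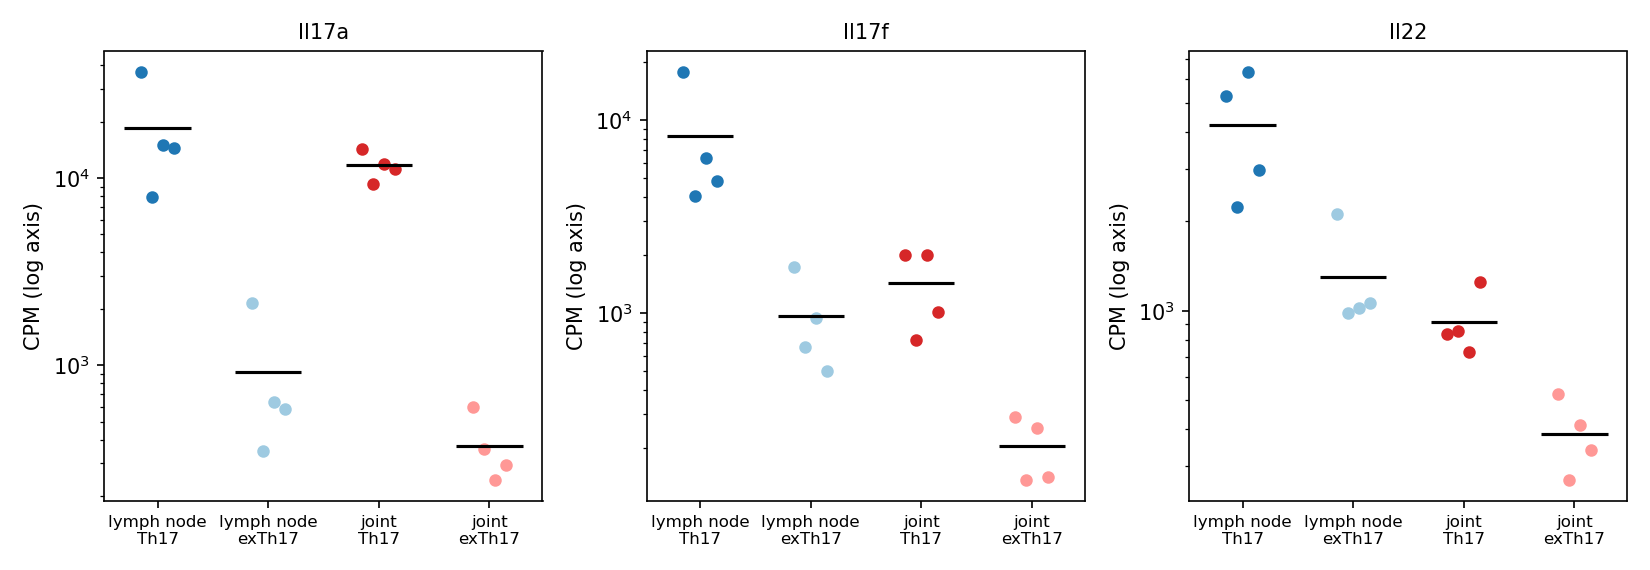
CPM of Il17a, Il17f and Il22 in each library (points, log axis), with the mean of each group of 4 (black lines). Il17a defined the sort; Il22 averaged 4204 CPM in lymph node Th17 and 386 CPM in joint exTh17 libraries.

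In lymph nodes 98 genes were called, 31 higher and 67 lower in exTh17 cells. The calls of Il17a, Iigp1, Gbp2 and Dusp1 held without each of the 8 libraries in turn. That of Il17f ended without exTh17 6 (adjusted p = 0.0574), that of Nr4a1 without Th17 1 or exTh17 6 (up to 0.0662), that of Tnfsf11 without Th17 1 or exTh17 2 or 6 (up to 0.0604), and that of Fos without Th17 1 or 13 or exTh17 2 or 6 (up to 0.0818). That of Il22 ended without Th17 1 or 9 or exTh17 6, 10 or 14 (up to 0.128), and that of Ltb without Th17 1 or 13 or exTh17 6 or 14 (up to 0.112). Tgtp1 lost its call without Th17 5, 9 or 13 or exTh17 2, 6 or 10 (up to 0.139), and Tgtp2 without Th17 1, 9 or 13 or exTh17 2 or 6 (up to 0.155). Csf2 lost it without Th17 1 or 13 or exTh17 2, 6, 10 or 14 (up to 0.195); Th17 1 held 322 CPM of Csf2, and without it the change was -4.01 (adjusted p = 0.181). The Csf2 call also ended on log2(TPM + 1) and with limma's sample quality weights. With sets of 4 consecutive sample numbers as a block, which the labels do not name, the count was 199. DESeq2 called 449 genes, limma with sample quality weights 246, and edgeR fitted to these 8 libraries alone 1, which was not among the 98. The count was 39 without Th17 1, 155 without Th17 5, 45 without Th17 13, 42 without exTh17 2 and 16 without exTh17 6.

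Of the gene lists, 10 were called in lymph nodes, and none held after adjustment with an estimated correlation between genes, where the lowest adjusted p was 0.0680. The estimated-correlation p of each list is given unadjusted. The stimulation response, early genes that PMA and ionomycin switch on, had a median of -1.47; 7 of 26 tested members fell, 18 adjusted over the list alone (camera adjusted p = 4.90e-14; estimated-correlation p = 0.00400). Inhibitory receptors and exhaustion genes had a median of -1.22, with 3 of 13 falling and, adjusted over the list alone, 7 falling and 1 rising (camera adjusted p = 6.57e-06, estimated-correlation p = 0.00341). The 3 were the receptor gene Pdcd1 and Nr4a2 and Nr4a3, which are also in the stimulation response list. This call therefore partly repeats that of the stimulation response. Effector cytokines and TNF family genes had a median of -1.48, with 1 of 21 rising and 2 falling, and 1 and 9 adjusted over the list alone (camera adjusted p = 4.00e-05; estimated-correlation p = 0.0111). The pathogenic Th17 signature had a median of -1.11, with 2 of 16 falling, 7 adjusted over the list alone (camera adjusted p = 6.23e-05; estimated-correlation p = 0.0184). The Th17 programme had a median of -0.38, with 3 of 20 falling and, adjusted over the list alone, 9 falling and 1 rising (camera adjusted p = 0.00242, estimated-correlation p = 0.107). The 3 were Il17a, which the sort fixed as lower, Il17f and Il22, and the list was not tested without Il17a. Without Th17 1 the median of this list was -0.12 (camera adjusted p = 0.0456). The chemokines had a median of -1.41; 0 of 16 passed, and 4 fell adjusted over the list alone (camera adjusted p = 6.57e-06; estimated-correlation p = 0.0380). The Treg programme had a median of -0.57, with 1 of 15 falling, and 3 falling and 2 rising adjusted over the list alone (camera adjusted p = 0.0369; estimated-correlation p = 0.0173). Its call ended without Th17 9 or 13 (adjusted p up to 0.103). The type I interferon response lay above 0, with a median of 0.48 and 13 of 19 folds positive; 0 members passed, and 1 rose adjusted over the list alone (camera adjusted p = 0.0374; estimated-correlation p = 0.401). That call ended without Th17 1, 5 or 9 or exTh17 2 or 14 (adjusted p up to 0.676), with a median of 0.15 without Th17 9 and 0.13 without exTh17 14; without Th17 13 the median was 0.86. Beside the chemokines, markers of macrophages had a median of -1.37, with 0 of 15 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00645; estimated-correlation p = 0.215). Their call ended without Th17 13 or exTh17 10 (adjusted p up to 0.0690). Those of dendritic cells had a median of -1.08; 0 of 11 passed, and 5 fell adjusted over the list alone (camera adjusted p = 0.00233; estimated-correlation p = 0.0702). Cd74, an antigen presentation gene, averaged 195 ± 38.6 against 391 ± 138 CPM (SD, n = 4 each).

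A contrast of the mean over both tissues asks which differences between exTh17 and Th17 cells stand with the tissue held fixed. Il17f, Il22 and Tnfsf11 fell in this mean, and so did Il1r2, the decoy receptor of interleukin 1, and Acly, which makes acetyl-CoA for lipid synthesis. Iigp1 rose. Of these only Il17f also passed in each tissue; the others passed in lymph nodes and not in the joint.

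Il22 changed by -1.47 ± 0.24 (adjusted p = 0.00723), Il17f by -2.95 ± 0.36 (7.88e-04), Tnfsf11 by -1.30 ± 0.26 (0.0171), Il1r2 by -1.27 ± 0.20 (0.00683), Acly by -1.27 ± 0.20 (0.00702) and Iigp1 by 1.45 ± 0.20 (0.00208). In the joint the changes were -0.58 ± 0.36 for Tnfsf11 (adjusted p = 0.614), -0.80 ± 0.27 for Il1r2 (0.157), -0.48 ± 0.28 for Acly (0.574), 0.65 ± 0.27 for Iigp1 (0.318) and -1.25 ± 0.34 for Il22 (0.0564). In lymph nodes they were -2.01 ± 0.37 for Tnfsf11, -1.74 ± 0.28 for Il1r2 (adjusted p = 0.0119), -2.06 ± 0.29 for Acly (0.00452), 2.25 ± 0.29 for Iigp1 and -1.70 ± 0.34 for Il22. The contrast called 262 genes, 181 higher and 81 lower. DESeq2 called 1001. Limma with sample quality weights called 23, of which 7 were higher and 16 lower, and among genes of mean log2 CPM of at least 5 edgeR called 36 higher and 85 lower, so the majority direction turned in both. The call of Tnfsf11 ended with the quality weights. The count was 96 to 174 without lymph node Th17 1, 5 or 13 or any 1 of the 4 lymph node exTh17 or the 4 joint exTh17 libraries. Joint and lymph node calls shared 0 genes higher in exTh17 cells, where 0.742 would be shared by chance (one-sided Fisher's exact p = 1). All 31 genes higher in lymph node exTh17 cells had a mean log2 CPM of at least 5, as did only 7 of the 326 in the joint. Few genes could therefore be shared, and the 0 says little about whether the tissues share changes. Lower calls shared 2 genes, Il17a, which the sort fixed as lower, and Il17f. Unadjusted p-values under 0.05 numbered 1650 in the joint and 1445 in lymph nodes.

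A test of the difference itself asks whether the change from Th17 to exTh17 cells depends on the tissue. For the Th17 cytokines no such difference was detectable: the joint change minus the lymph node change was 0.29 ± 0.68 for Il17f (adjusted p = 0.951) and 0.45 ± 0.47 for Il22 (0.825). Csf2 had a difference of 7.08 ± 1.67 (adjusted p = 0.0605), and Tnfsf11 of 1.44 ± 0.51 (0.212). Cnp, a nucleotide phosphodiesterase gene, Cyb5a, a cytochrome gene, and Ifi47, an interferon-inducible GTPase gene, differed between tissues, with larger changes in lymph nodes. The difference was -1.79 ± 0.37 for Cnp (adjusted p = 0.0351), -2.03 ± 0.42 for Cyb5a (0.0358) and -1.34 ± 0.30 for Ifi47 (0.0496).

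The call of Cnp ended without any 1 of the 8 exTh17 libraries or lymph node Th17 1, 9 or 13 (adjusted p up to 0.102). That of Cyb5a ended without those libraries or joint Th17 15 (up to 0.0940), and that of Ifi47 without any library but lymph node Th17 1 and joint Th17 15 (up to 0.122). All 3 calls ended on log2(TPM + 1) and by limma with sample quality weights, and that of Ifi47 also with the block of sets of 4 consecutive sample numbers. The test called 72 genes, 69 with a positive difference and 3 with a negative one. Most of the 69 were scarce, with a median log2 CPM of 1.18, against 3.97 for all tested genes. Trmt44 differed by 6.75 ± 0.74 (adjusted p = 5.05e-04) and kept its call without each of the 16 libraries; Relt differed by 5.55 ± 0.84 (0.0108) and lost it without lymph node exTh17 10 (0.0546). DESeq2 called 637 genes and limma with sample quality weights 0, with 1605 at an unadjusted p under 0.05. The count ran from 3 without lymph node exTh17 10 to 162 without joint Th17 3, and stayed within 1.5 times of 72 only without lymph node Th17 9, joint exTh17 8 or joint Th17 15. By camera 3 lists were called here, and none held after adjustment with an estimated correlation (lowest adjusted p = 0.227). Each estimated-correlation p below is unadjusted. Inhibitory receptors and exhaustion genes had a median difference of 1.14, with 1 of 13 rising, 6 adjusted over the list alone (camera adjusted p = 0.00119, estimated-correlation p = 0.0132). The stimulation response, which shares Nr4a2 and Nr4a3 with that list, had a median of 1.06, with 0 of 26 rising, 10 adjusted over the list alone (camera adjusted p = 0.00119, estimated-correlation p = 0.103). Cytotoxicity had a median of 0.69, with 0 of 13 rising, 2 adjusted over the list alone (camera adjusted p = 0.0297, estimated-correlation p = 0.0133). The call of cytotoxicity ended without joint Th17 3 or 11, joint exTh17 8, lymph node Th17 9 or lymph node exTh17 10 or 14 (adjusted p up to 0.145), and its median was 1.07 without joint Th17 7. Markers of NK cells lay above 0 as well, with a median difference of 3.18 and 6 of 6 positive; 0 passed over all genes, and 3 rose adjusted over the list alone (camera adjusted p = 0.244). Those of B and plasma cells had a median of 2.82, with 4 of 5 positive, 0 passing over all genes and 1 rising adjusted over the list alone (camera adjusted p = 0.0715, fry adjusted p = 0.0443).

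The comparison of joint with lymph node cells, within each cell type, asks what the inflamed tissue changes. In both cell types interferon response genes such as Isg15, Irf7 and Ifit1 rose in the joint, and so did Lag3, an inhibitory receptor of activated T cells, and Stat3, which relays cytokine signals. The type 2 cytokine gene Il5 and the growth factor gene Il3 fell in both, as did Il17f and Il22. Chemokine genes such as Cxcl10, Cxcl1 and Ccl2 rose together with fibroblast genes such as Dcn and macrophage genes such as Lyz2. In exTh17 cells the joint samples had more Csf2 and Tnf, and in Th17 cells they had less Cxcr3, a chemokine receptor gene of Th1 cells.

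Isg15 (ENSMUSG00000035692.7, mm10 chromosome 4, 156199424 to 156200818) averaged 1035 ± 109 CPM in joint and 40.9 ± 16.0 CPM in lymph node Th17 libraries (SD, n = 4 each; log2 fold change 4.66 ± 0.34, adjusted p = 8.52e-08). In exTh17 libraries it averaged 830.2 ± 87.2 against 31.4 ± 16.0 CPM (SD, n = 4 each; 4.72 ± 0.34, adjusted p = 1.24e-07). Lag3 (ENSMUSG00000030124.2, mm10 chromosome 6, 124904361 to 124911705) rose by 4.17 ± 0.33 in Th17 cells (adjusted p = 1.64e-07) and by 5.35 ± 0.35 in exTh17 cells (5.03e-08). Stat3 rose by 1.39 ± 0.20 (8.70e-05) and 1.83 ± 0.20 (5.63e-06). Il5 changed by -3.27 ± 0.66 in Th17 cells (adjusted p = 0.00191) and by -3.45 ± 0.67 in exTh17 cells (0.00146), and Il3 by -5.73 ± 0.70 (2.09e-05) and -4.27 ± 0.66 (2.47e-04). Il22 changed by -2.20 ± 0.34 in Th17 cells (2.47e-04) and -1.75 ± 0.34 in exTh17 cells (0.00154). Cxcr3 averaged 14.7 ± 11.1 against 90.6 ± 30.8 CPM in Th17 libraries (SD, n = 4 each; -2.63 ± 0.62, adjusted p = 0.00526); in exTh17 cells its change was -1.52 ± 0.59 (0.0852).

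Limma with sample quality weights ended the Th17 calls of Il5 and Il3 and the exTh17 call of Csf2. In exTh17 cells Csf2 rose by 4.23 ± 1.23 (adjusted p = 0.0220) by edgeR. Tnf rose from 72.2 ± 18.8 to 182 ± 81.4 CPM (SD, n = 4 each; adjusted p = 0.0135). The call of Tnf ended without lymph node exTh17 6 or joint exTh17 16 (up to 0.0687), and that of Csf2 without lymph node exTh17 6, 10 or 14 or joint exTh17 12 (up to 0.0751). The difference between the cell types in these changes did not pass for Csf2 (7.08 ± 1.67, adjusted p = 0.0605), Tnf (1.23 ± 0.50, 0.295) or Cxcr3 (1.11 ± 0.82, 0.705). Hey1, a Notch target gene (ENSMUSG00000040289.8, mm10 chromosome 3, 8663359 to 8667256), had 0 counts in all 4 joint Th17 libraries and was at least 277-fold lower there than in lymph node Th17 libraries, against a floor of 3 counts over the group. It was low elsewhere too, at 1.48 ± 1.24 CPM in joint exTh17 and 3.85 ± 1.40 CPM in lymph node exTh17 libraries (SD, n = 4 each), and joint Th17 libraries held fewer distinct genes, 14096 against 17843 in lymph node Th17 libraries. Joint and lymph node Th17 cells differed in 3326 genes, 1606 higher and 1720 lower in the joint; exTh17 cells differed in 2592, 1406 higher and 1186 lower. The lists of called genes shared 958 higher genes, against 166 for independent lists, and 674 lower genes, against 150. These pairs share no library, but both come from 1 fit with a shared estimate of the spread of each gene. The same genes are therefore easier to call in both, and the numbers for independent lists do not allow for this. Of 1639 genes called in both, 1632 changed in the same direction. Lymph node libraries of a set of 4 consecutive sample numbers correlated at 0.165 to 0.261, however. Lymph node Th17 and joint exTh17 libraries of a set did so at -0.010 to 0.282. The lists are therefore not fully independent. The Th17 count was 2045 by limma with sample quality weights and 1739 with only these 8 libraries in the fit, and the exTh17 count was 4131 and 3852. The majority direction turned for Th17 cells with quality weights (1084 higher, 961 lower), with only these 8 libraries (939 and 800) and among genes of mean log2 CPM of at least 5 (949 and 896), and for exTh17 cells among the last (859 and 1140) and without lymph node exTh17 6 (924 and 928). With any 1 library left out they ran from 2632 to 3549 and from 1807 to 2223.

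**Figure D3:**
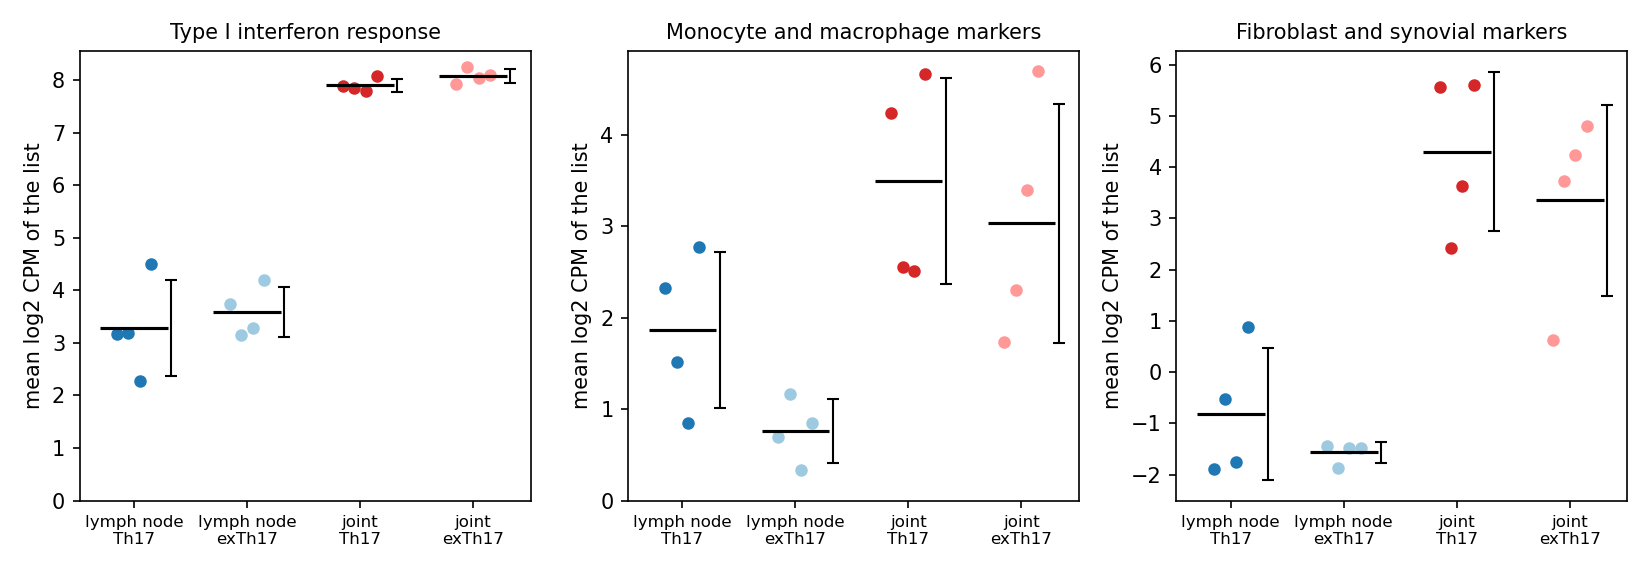
Mean log2 CPM of the type I interferon, macrophage and fibroblast lists in each library (points), with the mean (line) and SD (bars) of each group of 4. Over the 8 joint libraries the interferon level spans 0.45 log2 units, the macrophage level 2.96 and the fibroblast level 4.97.

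None of the list calls between tissues held after adjustment with an estimated correlation, where the lowest adjusted p was 0.118 in Th17 and 0.125 in exTh17 cells; each estimated-correlation p below is unadjusted. By lists, 18 of 19 interferon genes rose in the joint in each cell type, over all genes and adjusted over the list alone. The median was 4.66 in Th17 cells (camera adjusted p = 1.56e-24; estimated-correlation p = 0.00347) and 4.63 in exTh17 cells (camera adjusted p = 1.99e-23; estimated-correlation p = 0.00405). Chemokine genes rose in 7 of 16 cases in Th17 cells (11 rising and 1 falling adjusted over the list alone; median 2.12; camera adjusted p = 8.84e-04, estimated-correlation p = 0.0947). They rose in 9 cases in exTh17 cells (12 adjusted over the list alone; median 2.08; camera adjusted p = 1.80e-05, estimated-correlation p = 0.0478). Fibroblast markers moved with them: 14 of 16 rose in Th17 cells (14 adjusted over the list alone; camera adjusted p = 1.29e-09, estimated-correlation p = 0.0527). In exTh17 cells 13 rose (16 adjusted over the list alone; median 6.84; camera adjusted p = 5.55e-09, estimated-correlation p = 0.0601). Of 15 macrophage markers 7 rose in each cell type, and 9 and 11 adjusted over the list alone, with medians of 2.57 and 2.81. Their camera adjusted p was 0.00131 and 2.51e-04, and their estimated-correlation p 0.144 and 0.114, in Th17 and exTh17 cells; the exTh17 median was 1.77 without joint exTh17 16. Of 11 dendritic cell markers 6 rose in Th17 cells and 8 in exTh17 cells, the same numbers as adjusted over the list alone, with medians of 1.77 and 2.21. Their camera adjusted p was 0.0200 and 0.00152, and their estimated-correlation p 0.132 and 0.0654; the Th17 call ended without joint Th17 3 (adjusted p = 0.0617). Dcn averaged 309 ± 232 CPM in joint and 3.05 ± 3.73 CPM in lymph node Th17 libraries, Lyz2 176 ± 125 and 28.4 ± 14.5 CPM, and Cd74 1735 ± 529 and 391 ± 138 CPM (SD, n = 4 each).

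Heat shock genes, which rise when tissue is digested or cells are stressed, rose in the joint in 4 of 12 cases in Th17 cells (5 adjusted over the list alone; median 0.52; camera adjusted p = 0.0200, estimated-correlation p = 0.0588) and in 9 in exTh17 cells (9 adjusted over the list alone; median 1.39; camera adjusted p = 7.21e-05, estimated-correlation p = 0.00734). The call in Th17 cells ended without joint Th17 15 (adjusted p = 0.0888). Hspa1a averaged 166 ± 88.1 CPM in joint and 5.87 ± 3.88 CPM in lymph node exTh17 libraries (SD, n = 4 each); its reads can also come from the near-identical Hspa1b. In exTh17 cells 12 of 26 stimulation response genes rose and 2 fell, and 14 and 3 did so adjusted over the list alone (median 0.73; camera adjusted p = 0.00127, estimated-correlation p = 0.127). Of 20 Th1 programme genes 8 rose in exTh17 cells, with 8 rising and 1 falling adjusted over the list alone (median 1.00; camera adjusted p = 0.00666, estimated-correlation p = 0.0532); they include Nkg7, a cytotoxic granule gene (2.99 ± 0.43, adjusted p = 1.16e-04), and the median was 0.63 without joint exTh17 16. In Th17 cells 2 of 21 glycolysis and hypoxia genes rose, 1 adjusted over the list alone (median 0.34; camera adjusted p = 0.00489, estimated-correlation p = 0.343), among them the glucose transporter gene Slc2a3 (1.98 ± 0.47, adjusted p = 0.00573). That call ended without lymph node Th17 9 (median 0.16, adjusted p = 0.123), and the median was 0.57 without lymph node Th17 1 and 0.63 without lymph node Th17 5. The labels do not say how joints and lymph nodes were handled before the sort, and any difference in handling would coincide with the tissue.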

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

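The tests of sequencing depth, of genes chosen and read in separate libraries, of macrophage and fibroblast RNA, of tissue handling and of the IL-17A sort were chosen only after the result each measures was seen.

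Outlying libraries were sought in each group of 4, for 1 measure at a time. The measures were the CPM of set genes, the total count, the genes with a count and the share of the most abundant genes. In 9 of the 80 tests 1 library lay far from the other 3. This was judged by the ratio of its gap to the nearest other to the range of the group. About 4 such tests are due by chance if values are normally distributed, which CPM need not be. Lymph node exTh17 2 was the highest of its group in Il17a (2139 CPM, nearest 636, ratio 0.839) and in Il22 (2110 CPM, nearest 1059, ratio 0.934). Lymph node Th17 1 was the highest in Il17f (17766 CPM, nearest 6364, ratio 0.830) and in Ifng (55.7 CPM, nearest 11.5, ratio 0.915). Lymph node exTh17 10 was the highest in Ccl20 (24.4 CPM, nearest 7.90, ratio 0.934). Lymph node Th17 5 was the lowest in Tnf (65.2 CPM, nearest 193, ratio 0.910), and lymph node Th17 9 the lowest in Cd3e (142 CPM, nearest 240.2, ratio 0.884). In the joint, exTh17 16 was the highest in Cd4 (433 CPM, nearest 292, ratio 0.893) and exTh17 12 the lowest in Cd3e (375 CPM, nearest 388, ratio 0.886).

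The change from Th17 to exTh17 cells differed between joint and lymph nodes for 72 genes by the test of that difference. Of these, 69 had a positive difference, and their median log2 CPM was 1.18, against 3.97 for all tested genes. For such scarce genes, loss of transcripts in the joint Th17 libraries cannot be told apart from dependence on tissue. On the log2 scale, as joint minus lymph node, the difference was 6.75 for Trmt44, 5.55 for Relt, 5.95 for the histamine receptor gene Hrh2, 5.56 for the lipid transporter gene Mfsd2a and 5.45 for Sh2d5. It was -1.79 for Cnp, -2.03 for Cyb5a and -1.34 for Ifi47. The call of Hrh2 ended without lymph node exTh17 10 or 14, and that of Mfsd2a without lymph node exTh17 10 (edgeR adjusted p up to 0.0546 for each). That of Sh2d5 ended without lymph node exTh17 2, 6 or 10 or lymph node Th17 13 (up to 0.0728).

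Other splits of the same libraries into groups of the same sizes tested whether chance could give as many called genes. Of 35 splits, 1, the real one, gave as many as 347 genes in the joint (the highest other gave 2), 98 in lymph nodes (9), 3326 between Th17 groups (6) and 2592 between exTh17 groups (0). For the mean over tissues 1 of 100 splits gave 262 genes (the highest other gave 114). At these shares, each taken alone, chance is argued against in the joint, between tissues in each cell type and for the mean. For the mean this concerns only no change in either tissue. The shares were not adjusted over comparisons, and 1 of 35 is the smallest that 35 splits can give. The joint groups can differ in level or in spread, and the sort fixed a difference in Il17a between them. In lymph nodes libraries of a set of 4 consecutive sample numbers correlated, at 0.165 to 0.261; the 8 splits that part every such pair are too few for a share under 0.05, and the highest other of them gave 0. For the mean 24 of the splits did so, and the highest other of them gave 69. For the difference between tissues 2 of 100 splits gave 72 or more (the highest other gave 75). Mixing the cell types removes the changes themselves as well as their difference, so these splits decide nothing about dependence on tissue: those that kept the joint groups and mixed only the lymph node groups gave 75 and 49. Chance is not excluded for the number of lists called: 3 of 35 splits gave the 6 of the joint or more (the highest other gave 7), 10 gave the 10 of lymph nodes (16), 9 gave the 7 between Th17 groups (12) and 14 gave the 8 between exTh17 groups (13).

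In the joint 326 genes were higher and 21 lower in exTh17 cells, and the joint Th17 libraries held few distinct genes. Lower depth is argued against, since joint Th17 libraries held 1.17 times the mean total count of joint exTh17 libraries. Libraries drawn from the joint exTh17 profile through 1995262 molecules, which left 14019 genes with a count, gave a mean of 0.1 higher calls over 10 draws and at most 1. Yet random loss of transcripts cannot be told apart from a difference between the cells, since the simulation rests on an assumed profile, and the median fold of genes chosen with 2 libraries of each joint group moved from 4.81 to 5.19 there to 0.22 to 1.32 in the other 2. Loss of the same transcripts in every joint Th17 library was not simulated, and a biological difference between the cells was not tested; both stay open, and either could give Trmt44 its near absence from joint Th17 libraries alone.

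Interferon response genes were higher in joint than in lymph node cells of both types, and RNA of macrophages or fibroblasts, which the tdTomato sort should remove, could bring such transcripts. Within the joint groups the interferon level rose by 0.0508 for each log2 unit of the macrophage list (0.0238 to 0.0755 with 1 library left out) and by 0.0481 for each unit of the fibroblast list (0.0348 to 0.0573), where other cells as the source would need about 1, so both are argued against. The joint libraries did hold some such RNA, with Col1a1 at 99.1 and Dcn at 102 CPM in joint exTh17 libraries and Lyz2 at 83.4 and Cd74 at 905 CPM; of the 15 macrophage and 16 fibroblast genes tested, 5 and 1 also averaged at least 10 CPM in lymph node libraries, and 0 are in the interferon list. Handling of joint tissue cannot be told apart from the tissue itself, since the labels do not describe it, any difference would coincide with the tissue, and 9 of 12 heat shock genes rose in joint exTh17 cells. Interferon in the inflamed joint was not tested and stays open.

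Stimulation response genes were lower in lymph node exTh17 than Th17 cells, with a list median of -1.47. A single strongly stimulated library is argued against, since the median without lymph node Th17 1 was -1.24. The sort itself, which takes cells that responded with IL-17A, could give this difference in both tissues, where the joint median was -0.12. The difference between tissues had a median of 1.06 with p = 7.03e-05 by camera and 0.00913 by fry, and p = 0.103 by camera with an estimated correlation, so the sort cannot be told apart from a difference between the cells. A weaker response of lymph node exTh17 cells stays open.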

How the results depend on the processing

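The settings with only genes of mean log2 CPM of at least 5, with the number of genes with a count as a covariate, and without samples 1 and 2 were chosen after seeing the data, the last from their measured Il2 and Il17a; the others were planned. Counts are for the joint, lymph node, Th17, exTh17, mean and difference comparisons, of 347, 98, 3326, 2592, 262 and 72 genes. Values not given here stayed within 1.5 times of these, as did all counts with RLE factors, library size alone, a stricter filter, no robust estimation and log2(TPM + 0.1), though the lower genes of the joint were 9 with library size alone, 12 with the stricter filter and 6 on log2(TPM + 0.1), against 21. Of the 244 results for named genes, 163 were called. None of these reversed direction with RLE factors, DESeq2, limma with quality weights, log2(TPM + 1), the block or 1 library left out. Changes of sign in results not called were not counted, and named genes were not followed in the other settings. None of the 31 called list results reversed with an estimated correlation, fry, RLE factors, the block or 1 library left out.

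Without a filter on low counts the joint count was 187, the mean 166 and the difference 21. With sets of 4 consecutive sample numbers as a block, which the labels do not name, the joint count was 178, lymph node 199 and difference 17. Of the named calls it lost 7 of 19 in the joint (Cyp51, Dus2, Entpd7, Haspin, Mmp12, S1pr4 and Vcam1), 1 of 8 for the difference (Ifi47) and 0 in the other comparisons. Libraries of a set correlated across genes at 0.165 to 0.261 in lymph nodes (exact one-sided p = 0.0417 over 24 pairings) and at -0.048 to 0.142 in the joint (p = 0.292). With only the compared groups in the fit the counts were 1 in the joint, 1 in lymph nodes and 1739 for Th17. At an adjusted p under 0.1 they were 582, 188, 566 for the mean and 306 for the difference. Against a fold of 1.5 they were 4 in lymph nodes, 2053 for Th17, 1352 for exTh17 and 48 for the mean. DESeq2 gave 1072, 449, 1001 for the mean and 637 for the difference. Limma voom with sample quality weights gave 1, 246, 2045, 4131, 23 and 0, the last with 1605 at an unadjusted p under 0.05. It gave the joint Th17 libraries weights of 0.276 to 0.559 and lymph node Th17 9 a weight of 0.405. It lost 18 of the 19 named calls in the joint (all but Il17a), 2 of 27 in lymph nodes (Areg and Csf2), 5 of 46 for Th17 (Il2, Il23r, Il3, Il31 and Il5), 2 of 50 for exTh17 (Csf2 and Mir6236), 4 of 13 for the mean (Tnfsf11 among them) and 8 of 8 for the difference. On log2(TPM + 1) the joint count was 200, the mean 151 and the difference 34. It lost 8 of 19 named calls in the joint (Cyp51, Dus2, Entpd7, Hsph1, Lef1, Mmp12, Rrp15 and Vcam1), 2 of 27 in lymph nodes (Areg and Csf2), 1 of 46 for Th17 (Il23r), 1 of 50 for exTh17 (Ccr6), 1 of 13 for the mean and 5 of 8 for the difference (Cnp, Cyb5a, Hrh2, Ifi47 and Sh2d5). RLE factors lost 1 in the joint (Cyp51) and DESeq2 none. The split of higher and lower calls moved with the unit: for exTh17 it was 1599 and 879 on log2(TPM + 1) and 1501 and 796 on log2(TPM + 0.1), against 1406 and 1186, and for the mean 160 and 38 on log2(TPM + 0.1), against 181 and 81.

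Genes of mean log2 CPM of at least 5 gave 1, 241, 1845, 121 for the mean and 0 for the difference by edgeR, the last with 673 at an unadjusted p under 0.05; fewer genes are tested. The majority was then lower for the mean (36 higher, 85 lower) and exTh17 (859 and 1140) and higher for Th17 (949 and 896, against 1606 and 1720). Limma with quality weights gave 7 and 16 for the mean and 1084 and 961 for Th17. With the number of genes with a count as a covariate, the joint count was 53, Th17 1292, mean 59 and difference 4; that number differs between groups, so the covariate takes up part of their difference. Without samples 1 and 2 lymph nodes gave 15. The looser threshold and the fold minimum act by construction; for the other settings the cause was not tested. Depth limits the scarce genes most, and the genes higher in joint exTh17 cells had a median log2 CPM of 0.29.

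With 1 library left out the counts ran from 223 (joint exTh17 16) to 430 (joint Th17 3) in the joint, 16 (exTh17 6) to 155 (Th17 5) in lymph nodes, 2632 to 3549 for Th17, 1807 to 2223 for exTh17, 96 (lymph node Th17 13) to 328 (joint Th17 7) for the mean, and 3 (lymph node exTh17 10) to 162 (joint Th17 3) for the difference. The 31 list calls ran from 28 to 37 and became 0 with an estimated correlation.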

Other observations

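The test of further GTPase genes was planned before their lymph node values were seen; its repeat without Gbp6 and Gbp7 was chosen after the result was seen.

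Interferon-inducible GTPase genes were among those highest in lymph node exTh17 against Th17 cells (Iigp1, Gbp2, Tgtp1, Tgtp2), which led to the hypothesis that other members of these families are higher too. The 11 further members tested had a median log2 fold change of 0.82, and 10 were positive. Of these, 2 passed over all genes tested, Igtp (1.56 ± 0.28, adjusted p = 0.0145) and Gbp6 (1.16 ± 0.26, adjusted p = 0.0490), and 4 passed adjusted over the list alone. The camera p was 3.71e-06, and 0.0288 with an estimated correlation. Gbp6 and Gbp7 had already been seen among genes called between joint and lymph node Th17 cells, a comparison that shares the 4 lymph node Th17 libraries. Without them the other 9 had a median of 0.69, 8 positive folds, 1 gene passing over all genes and 2 adjusted over the list alone, with a camera p of 3.62e-04, and 0.0547 with an estimated correlation. Reads of Gbp6, Gbp10 and Gbp11, which are close in sequence, can be assigned to one another. The values may reflect a family-wide difference, but they come from the same libraries in which the pattern was found.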
